A study of Rattus norvegicus with 4 samples.

How the data were processed

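Gene expression in knee joint cartilage of male Sprague-Dawley rats was measured on 4 single-colour (Cy3) Agilent rat arrays, 2 from healthy controls and 2 from joints given leptin. Per the labels, total RNA was purified with DNase treatment, amplified and labelled before hybridization. Each deposited array file is the output of Agilent Feature Extraction 10.7, a version credited to the submitters' processing notes. Per the file headers, its processed signal is an intensity after background subtraction (spatial detrending with negative controls) and multiplicative detrending, with dim spots set to a surrogate value and no scaling between arrays. The same deposited files hold the mean signal and the local background of each spot, each an intensity, and yes-or-no quality calls of the scanner software. The authors also deposited a value table on the log2 scale with a value per probe. Each of its columns followed the log2 processed signal of its own array across 41012 probes (Pearson r of 0.998 or above, across probes, which are not independent replicates), and the column medians lay between 4.85 and 4.86. How that table was normalized between arrays is not given in the sources used here.

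Each array held 45018 spots, of which 43379 were not controls and served 41012 probes of 60 bases. Between 91 and 138 spots per array that the scanner software marked as uneven or as outliers were left out, no spot was saturated (0 on each array), and the remaining spots of a probe were averaged. Probe positions are those of rn4 (RGSC 3.4), the build named in the file headers. Gene symbols were brought up to date through RefSeq accessions for 18028 probes, while 3168 kept a current symbol, 400 were matched by a unique synonym, 1288 kept the symbol of the file and 18128 had none. The 22884 probes with a symbol covered 17542 genes.

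The main value was the log2 processed signal minus the 75th percentile of the same array. A probe was tested if the scanner software called it well above background on both arrays of at least 1 group. This left 24438 probes, 15374 of them with a symbol, and 11615 genes, each read by its tested probe with the highest mean signal over the 4 arrays. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a constant prior variance, 2 residual degrees of freedom and 3.11 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 24438 probes, with a threshold of 0.05. A gene took the adjusted p of its probe, so gene calls also depend on probes without a symbol. Adjustment over the 11615 genes alone was not run. Genes at least 2-fold apart in every pair of a leptin and a control array were counted as well, without a test. An exact permutation test of 2 against 2 arrays cannot give a two-sided p under 0.333, so none was used for single values.

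For a gene not well above background on either array of a group, the fold is given as a bound. The other group's mean is set against the dim group's mean of, for each array, the higher of the gene's signal and the lowest signal that was well above background. A bound is written as at least N-fold.

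Gene lists for 31 pathways and cell types were tested with camera (limma, preset correlation between genes of 0.01) on the 11615 genes, with p-values adjusted over the 31 lists. They covered cartilage matrix, hypertrophy, proteases and their inhibitors, inflammatory mediators, leptin and JAK-STAT, Wnt, TGF-beta and BMP, and IGF and FGF signalling. They also covered lysyl oxidases and collagen crosslinking, apoptosis, autophagy, glycolysis, oxidative phosphorylation, ribosomal proteins, cell cycle, immediate early genes, the unfolded protein response, the interferon response and antioxidant defence. Markers of other cells covered adipocytes, muscle, red cells, neutrophils, macrophages, lymphocytes, osteoblasts, osteoclasts, fibroblasts, endothelium and Schwann cells. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, were run beside it.

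Named genes followed a rule. It takes the called genes with both arrays of the higher group above both of the other and well above background there, up to 12 per direction, passing over provisional symbols and olfactory or vomeronasal receptors. It adds up to 4 called members of each list, or the 2 brightest where fewer than 2 were called, and 18 fixed genes. The groups, tests, lists, rule and alternatives were chosen before the data were examined.

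The alternatives were normexp background correction (offset 50) of the mean signal and local background, quantile normalization, scaling to the median, and the deposited value table in place of the main value. Further alternatives were no filter on dim probes, a filter asking for signal well above background on all 4 arrays, an eBayes variance trend, a block for the replicate number of the titles, the mean of all tested probes of a gene, and leaving out each array in turn. The pipeline was tested on simulated data with 200 changed genes among 11615 in 20 simulations. Of simulated 2-fold changes 3.02% were called, of 4-fold changes 74.9% and of 8-fold changes 92.1%, with a mean of 5.45 false calls. The simulated genes varied independently, without a slide or background effect, and were adjusted over the 11615 genes. These rates therefore need not hold for the calls in the real data. Tables were prepared in version 1.17.8 of data.table, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures in matplotlib 3.10.9.

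The probes well above background numbered 24356 and 25078 on the control arrays and 21567 and 26643 on the leptin arrays, and the number of arrays limits the precision. All 4 deposited arrays were used. The numbers in the names of the leptin array files are 2 and 3 where the titles have 1 and 2, and no reason for this is given in the sources used here. The control arrays shared slide 1 and the leptin arrays slide 2, so no fit with slide as a term can be had.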

Results

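Leptin, a hormone of fat cells that acts through its receptor Lepr and the JAK-STAT pathway, was injected at 100 µg in 50 µL of saline into the knee joint of rats, and cartilage was taken 24 hours afterwards. Genome-wide expression was read on 2 arrays of leptin-treated cartilage and 2 arrays of cartilage from healthy controls. Each group is described as 12 rats, and nothing states how these map onto the arrays. The limma p-values therefore measure only the spread between these arrays. For a gene dim on both arrays of a group, that spread is of signals not well above background, which may hold surrogate values. The p-values of camera also rest on the preset correlation of 0.01, which treats the genes of a list as nearly independent. The estimated correlation was 0.53 for the neutrophil list, 0.84 for the red cell list and −0.04 for the osteoblast list. For the osteoblast list the unadjusted camera p still went from 0.0152 with the preset to 0.118 with the estimated correlation. For the lysyl oxidase list, with an estimate of 0.007, it went from 0.000596 to 0.0722. The size of the correlation alone therefore does not account for the weaker results with an estimated correlation. The labels do not say what the control joints received, so nothing shows whether an effect of the injection itself is separated from that of leptin.

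Of 41012 probes, 59.4% and 61.2% were well above background on control arrays 1 and 2, and 52.6% and 65.0% on leptin arrays 1 and 2. The median local background was 29.0 and 28.0 intensity units on the control arrays and 35.5 and 36.0 on the leptin arrays. Negative control spots had a median signal of 45.05 and 44.73 units on the control arrays and 67.8 and 66.2 on the leptin arrays. Across probes, Pearson's r of log2 signal was 0.987 between the control arrays, 0.979 between the leptin arrays and 0.964 to 0.973 across groups, and probes are not independent replicates. The groups lay on separate slides with separate scans, so batch and group cannot be told apart.

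The comparison asks which genes change expression in articular cartilage in response to leptin. In the main scaling, transcripts of blood-forming and immune lineages made up the highest medians of the 31 gene lists. The neutrophil list had a median log2 fold change of 3.72, the red cell list 2.19 and the macrophage list 1.79, while the lymphocyte list had 2.55, which turned to −0.11 with normexp background correction. The interferon-response and osteoclast lists had medians of 1.21 and 1.08. The red cell median was 0.55 and the interferon median 0.15 with normexp background correction, under those of proteases (0.91), protease inhibitors (0.90), oxidative phosphorylation (0.83), ribosomal (0.76) and glycolysis genes (0.74). Among single genes, the secreted glycoprotein Chi3l1 rose 5.31-fold and the small proteoglycan lumican, Lum, rose 3.35-fold, calls that held in 6 and 3 of 13 alternatives. Cartilage matrix genes as a list had a median of −0.37, which became 0.49 with normexp background correction.

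**Figure D1:**
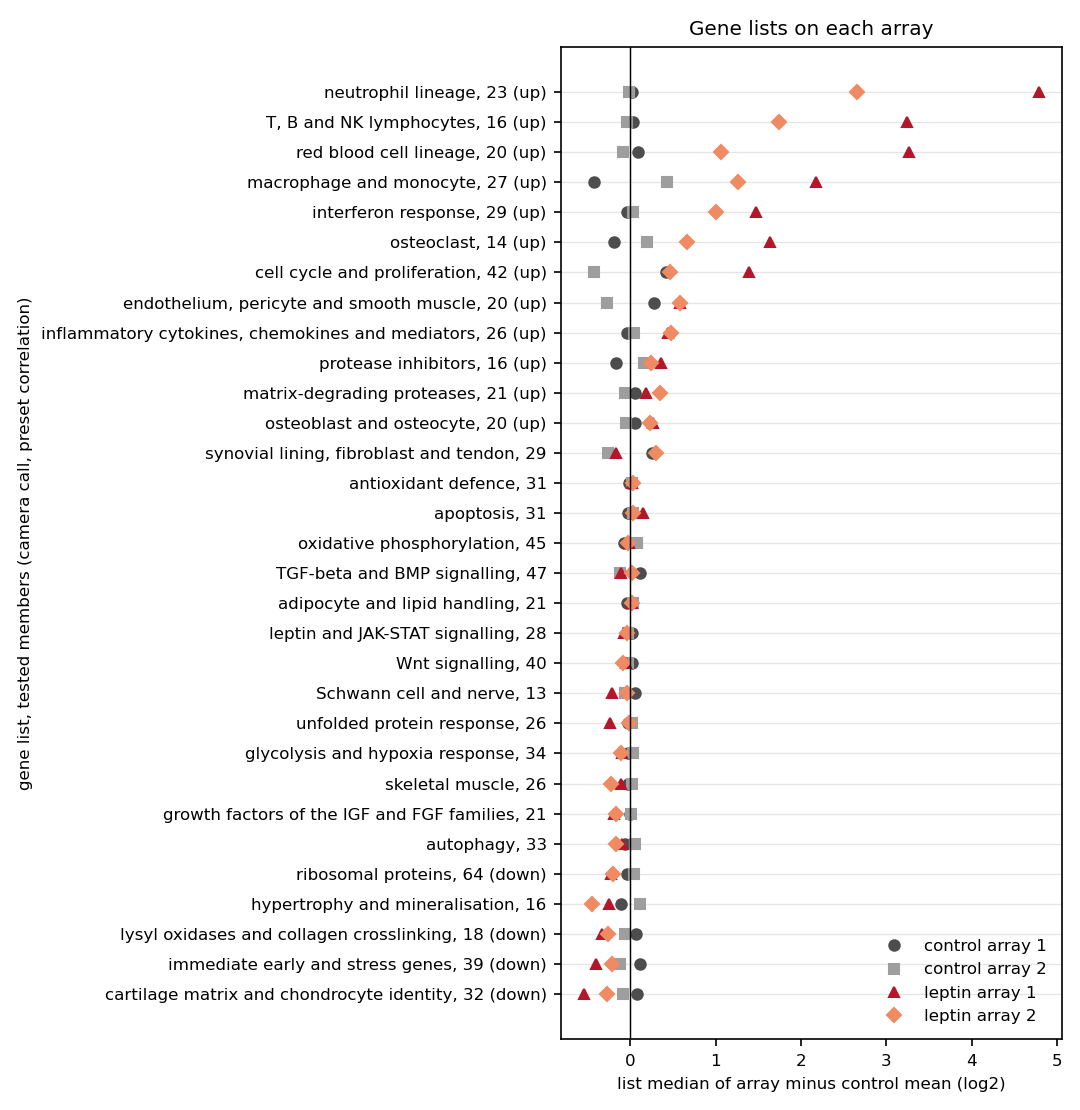
Median of each of the 31 gene lists on each array, minus the mean of the control arrays (x axis, log2 units), with the number of genes tested and the camera call beside each list name. The neutrophil list stood at 4.79 on leptin array 1 and 2.65 on leptin array 2, and among the called lists the medians of the lymphocyte, endothelial, cartilage matrix, lysyl oxidase and ribosomal lists changed sign with normexp background correction, the ribosomal median also with quantile normalization.

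With limma p-values adjusted over all 24438 probes, Cd2 of the lymphocyte list and Lum of the cartilage matrix list rose. Wnt1 of the Wnt list fell, and no other list member passed. Counts at an unadjusted p under 0.05 and counts adjusted over the list alone are therefore given for each list. List members named in addition to the 2 brightest and the genes of the rule were chosen after their values were seen. By chance, 16.7% of genes would have both leptin arrays above both control arrays.

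Neutrophil genes rose as a group (23 tested, camera adjusted p = 1.17e-18, adjusted p = 0.437 with an estimated correlation). Both leptin arrays lay above both control arrays for 21 of them, 19 were higher at an unadjusted p under 0.05, and 19 passed adjusted over the list alone. With the 6 members that were dim in controls set at their bound, the median was 3.05. The defensin Defa5 had a normalized log2 signal of 1.65 ± 0.07 (SD, n = 2) in controls and 7.47 ± 1.70 (SD, n = 2) with leptin, a log2 fold change of 5.81 (adjusted p = 0.0632). S100a9, a subunit of calprotectin, differed by 4.48 (adjusted p = 0.0618), and the bound for neutrophil elastase, Elane, was at least 29.6-fold over control (adjusted p = 0.0692). This bound was at least 12.5-fold without leptin array 1 and at least 70.0-fold without leptin array 2, and the log2 fold change of Elane was 1.73 with normexp background correction. Anxa1, an inhibitor of phospholipase that many cells make, differed by 0.13. Leptin array 1 lay above leptin array 2 for 21 of the 23 genes, and the list median was 2.65 without leptin array 1, 4.79 without leptin array 2 and 1.51 with normexp background correction.

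Red cell genes rose too (20 tested, camera adjusted p = 2.51e-11, adjusted p = 0.437 with an estimated correlation). Both leptin arrays lay above both control arrays for 18 genes, 14 were higher at an unadjusted p under 0.05, and 6 passed adjusted over the list alone. The median with 4 members at their bound was 2.01. Ahsp, the chaperone of alpha globin, differed by 2.94 (adjusted p = 0.222) and Klf1, the transcription factor of red cell precursors, by 2.99 (adjusted p = 0.195), or by 0.53 with normexp background correction. Without leptin array 1 Ahsp differed by 1.59 and Klf1 by 1.71, and without leptin array 2 by 4.28 and 4.27. The beta globin gene Hbb-b1 differed by 0.61 (adjusted p = 0.537) and Urod, an enzyme of haem synthesis, by 0.34 (adjusted p = 0.577). All 20 genes were higher on leptin array 1 than on leptin array 2, and the list median was 1.07 without leptin array 1 and 3.34 without leptin array 2. It was 0.55 with normexp background correction and 1.16 with the filter on all 4 arrays.

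Lymphocyte genes rose in the main scaling (16 tested, camera adjusted p = 4.28e-09, adjusted p = 0.437 with an estimated correlation), a call that ended with normexp background correction, where the median was −0.11. Of these, 12 had both leptin arrays above both control arrays, 11 were higher and 1 lower at an unadjusted p under 0.05, and 11 rose and 1 fell adjusted over the list alone. The median with 7 members at their bound was 1.78. Cd2, an adhesion molecule of T and NK cells, was called. The B cell precursor gene Igll1 had a bound of at least 13.9-fold over control (adjusted p = 0.0617), but the bound was at least 7.92-fold without leptin array 1 and at least 24.3-fold without leptin array 2, and its log2 fold change was 0.86 with normexp background correction. Nkg7, a granule gene of cytotoxic cells, differed by 4.54 (adjusted p = 0.0887) and the T cell kinase Zap70 by −0.33 (adjusted p = 0.657). Leptin array 1 lay above leptin array 2 for 14 of the 16 genes, and the list median was 1.63 without leptin array 1 and 3.24 without leptin array 2. It was 1.30 with no filter on dim probes and 1.53 with the filter on all 4 arrays.

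Macrophage and monocyte genes rose (27 tested, camera adjusted p = 1.17e-18, adjusted p = 0.437 with an estimated correlation). Both leptin arrays lay above both control arrays for 25 genes, 23 were higher at an unadjusted p under 0.05, and 22 passed adjusted over the list alone. The median with 3 members at their bound was 1.74. The complement gene C1qb differed by 1.81 (adjusted p = 0.0636), lysozyme, Lyz2, by 2.52 (adjusted p = 0.154) and the signalling adaptor Tyrobp by 1.83 (adjusted p = 0.194). Leptin array 1 lay above leptin array 2 for 23 genes, and the list median was 1.14 with normexp background correction. Osteoclast genes rose (14 tested, camera adjusted p = 2.73e-07, adjusted p = 0.437 with an estimated correlation), with 8 higher at an unadjusted p under 0.05 and 7 passing adjusted over the list alone. The collagen-cleaving cathepsin Ctsk differed by 2.06 (adjusted p = 0.148), the acid phosphatase Acp5 by 1.41 (adjusted p = 0.162) and the proton pump subunit Atp6v0d2 by 2.04 (adjusted p = 0.128). Leptin array 1 lay above leptin array 2 for 13 of the 14, and the list median was 0.66 without leptin array 1 and 1.64 without leptin array 2.

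Interferon-response genes rose (29 tested, camera adjusted p = 1.17e-18, adjusted p = 0.437 with an estimated correlation). Both leptin arrays lay above both control arrays for 26 genes, 23 were higher and 1 lower at an unadjusted p under 0.05, and 23 rose and 1 fell adjusted over the list alone. The ubiquitin-like protein gene Isg15 differed by 1.82 (adjusted p = 0.0799), the transcription factor gene Irf7 by 1.82 (adjusted p = 0.0823) and Isg20, an exonuclease, by −0.68 (adjusted p = 0.158), or by 0.26 with normexp background correction. B2m, the light chain of class I MHC, differed by 0.54 (adjusted p = 0.233) and the proteasome subunit Psmb10 by 0.31 (adjusted p = 0.631). With normexp background correction the list median was 0.15. Leptin array 1 lay above leptin array 2 for 19 of the 29 genes, with a median gap of 0.21.

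Cell cycle genes rose (42 tested, median 0.89, camera adjusted p = 2.91e-11, adjusted p = 0.437 with an estimated correlation), a call that ended with normexp background correction, where the median was 0.16. By limma, 15 were higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. In 22 genes both leptin arrays lay above both control arrays, and the groups overlapped for 20. Control array 1 lay above control array 2 by a median of 0.85, about as much as the groups differed. The proliferation marker Mki67 differed by 1.58 (adjusted p = 0.436), or by 0.68 without leptin array 1, 2.48 without leptin array 2, 0.80 without control array 2 and 0.87 with normexp background correction, and the cyclins Ccnd2 and Ccnd1 by −0.32 and −0.34. Leptin array 1 lay above leptin array 2 for 38 of the 42 genes, and the list median was 0.47 without leptin array 1 and 1.40 without leptin array 2. Of 17 marrow-stage precursor markers picked from the neutrophil, red cell and lymphocyte lists after the result was seen, 12 were tested, and all 12 lay higher on both leptin arrays than on both control arrays and higher on leptin array 1 than on leptin array 2.

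Matrix-degrading proteases rose as a list (21 tested, median 0.27, camera adjusted p = 0.000587, adjusted p = 0.437 with an estimated correlation), a call that ended without control array 2, where the median was 0.13. The median was 0.63 without control array 1, 0.91 with normexp background correction and 0.69 with no filter on dim probes. Of these, 6 were higher at an unadjusted p under 0.05, and 4 passed adjusted over the list alone. The list shared 2 tested members with the osteoclast list, among them Ctsk (2.06), and 1 each with the neutrophil and macrophage lists. The osteoclast list also shared 1 with the neutrophil list and 1 with the red cell list, and the inflammatory list 1 with the neutrophil list. The rises of these lists are therefore not independent. Collagenase 3, Mmp13, which cleaves type II collagen, had a log2 signal of 5.10 ± 0.28 (SD, n = 2) in controls and 6.05 ± 0.35 (SD, n = 2) with leptin, a difference of 0.95 (adjusted p = 0.189). Over the alternatives this difference ran from 0.70 to 1.85. Stromelysin 1, Mmp3, differed by 0.997 (adjusted p = 0.348) and the aggrecanase Adamts5 by 0.21 (adjusted p = 0.904). Without control array 1 Mmp3 differed by 1.55 and Adamts5 by 0.95, and without control array 2 by 0.45 and −0.53. The lysosomal cathepsins Ctsb and Ctsd, the brightest of the list, differed by 0.13 and −0.26. Protease inhibitors rose as a list (16 tested, median 0.29, camera adjusted p = 0.0132, adjusted p = 0.437 with an estimated correlation), a call that ended with no filter on dim probes and without control array 1, where the median was 0.03, or leptin array 2. With normexp background correction the median was 0.90. Of these, 4 were higher and 1 lower at an unadjusted p under 0.05, and 3 passed adjusted over the list alone. The broad inhibitor A2m differed by 2.21 (adjusted p = 0.0712), cystatin C, Cst3, by −0.06 and Timp2 by 0.10.

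Inflammatory cytokines, chemokines and mediators rose as a list (26 tested, median 0.40, camera adjusted p = 0.00219, adjusted p = 0.437 with an estimated correlation), a call that ended with normexp background correction, where the median was 0.18, and the median was −0.02 with the filter on all 4 arrays. It was 0.88 with no filter on dim probes, 0.71 without control array 2, 0.96 without leptin array 1 and 0.87 without leptin array 2. At an unadjusted p under 0.05, 12 were higher and 1 lower, and 10 rose and 1 fell adjusted over the list alone. The bound for the cytokine Il1b was at least 2.43-fold over control (adjusted p = 0.0566), though its log2 fold change was −0.48 with normexp background correction, and the chemokine Cxcl12, which retains blood-forming cells in marrow, differed by 3.22 (adjusted p = 0.0593). The brightest members, Cxcl14 and Lcn2, an iron-binding protein of neutrophils, differed by −0.39 (adjusted p = 0.379) and 1.61 (adjusted p = 0.255), the latter by 2.39 without control array 1 and 0.83 without control array 2. Ptgs2, the inducible cyclooxygenase, differed by −0.89 (adjusted p = 0.184). Il6, Nos2 and Lep were not well above background on any array and were not tested.

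Endothelial, pericyte and smooth muscle genes rose in the main scaling (20 tested, median 0.48, camera adjusted p = 0.00684, adjusted p = 0.521 with an estimated correlation), a call that ended with normexp background correction, where the median was −0.10, and without control array 2 or leptin array 2. The median was 0.90 without leptin array 1 and 0.72 with no filter on dim probes. Of the 20, 7 were higher and 2 lower at an unadjusted p under 0.05, and 5 rose and 1 fell adjusted over the list alone. The tight junction gene Cldn5 differed by 1.78 (adjusted p = 0.109), or by −0.23 with normexp background correction, and Notch3, a receptor of pericytes, and the endothelial transcription factor Erg by −0.30 and −0.40. Osteoblast and osteocyte genes rose as a list (20 tested, median 0.14, camera adjusted p = 0.0294, adjusted p = 0.437 with an estimated correlation), a call that ended with no filter on dim probes and without control array 1, leptin array 1 or leptin array 2. The median was 0.23 without leptin array 1, 0.26 without leptin array 2 and 0.31 with quantile normalization. It was 0.30 in the deposited value table or with the mean of probes, and 0.51 with normexp background correction. Its members included 4 that were higher at an unadjusted p under 0.05, and 1 passed adjusted over the list alone. This was osteocalcin, Bglap, with a log2 signal of 5.60 ± 0.23 (SD, n = 2) in controls and 8.64 ± 0.67 (SD, n = 2) with leptin (adjusted p = 0.0566). Type I collagen, Col1a2 and Col1a1, differed by 0.05 and 0.28.

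Cartilage matrix and chondrocyte genes fell as a list in the main scaling (32 tested, median −0.37, camera adjusted p = 0.000385, adjusted p = 0.437 with an estimated correlation), but with normexp background correction the list rose, with a median of 0.49. The call also ended with quantile normalization and in the deposited value table. At an unadjusted p under 0.05, 10 were lower and 1 higher, and 1 fell and 1 rose adjusted over the list alone. Type II collagen, Col2a1, had a log2 signal of 11.07 ± 0.10 (SD, n = 2) in controls and 10.82 ± 0.25 (SD, n = 2) with leptin, a difference of −0.25 (adjusted p = 0.664). Aggrecan, Acan, differed by −0.65 (adjusted p = 0.365), the chondrocyte transcription factor Sox9 by −0.48 (adjusted p = 0.281), biglycan, Bgn, by −0.35 (adjusted p = 0.468) and the type IX collagen chain Col9a3 by −1.03 (adjusted p = 0.0858). Acan read 6.91 and 7.59 on control arrays 1 and 2, against a leptin mean of 6.60, and differed by −0.99 without control array 1. With normexp background correction Col2a1 differed by 0.77, Acan by 0.33, Sox9 by 0.52, Bgn by 0.66 and Col9a3 by −0.06. That correction also moved the median of oxidative phosphorylation genes from −0.02 to 0.83, of ribosomal genes from −0.21 to 0.76 and of glycolysis genes from −0.14 to 0.74. It lowered others, such as that of red cell genes from 2.19 to 0.55. The upward turn was therefore not particular to the cartilage matrix or lysyl oxidase lists.

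Lysyl oxidases and collagen crosslinking enzymes fell as a list in the main scaling (18 tested, median −0.32, camera adjusted p = 0.00168, adjusted p = 0.437 with an estimated correlation), but rose with normexp background correction, with a median of 0.54. The call also ended with quantile normalization, in the deposited value table and without control array 1. By limma, 3 were lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The lysyl oxidase Loxl3 had a log2 signal of 3.98 ± 0.18 (SD, n = 2) in controls and 3.58 ± 0.57 (SD, n = 2) with leptin, a difference of −0.39 (adjusted p = 0.655), or of 0.44 with normexp background correction. It read 3.18 on leptin array 1 and 3.98, the control mean, on leptin array 2. Loxl4 differed by −0.93 (adjusted p = 0.169), or by −0.38 with that correction, and the prolyl hydroxylases P3h3 and P3h1 by −0.39 and −0.47.

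Ribosomal protein genes fell as a list in the main scaling (64 tested, median −0.21, camera adjusted p = 9.16e-06, adjusted p = 0.437 with an estimated correlation), rose with normexp background correction, with a median of 0.76, and had medians of 0.01 with quantile normalization and −0.01 in the deposited value table. At an unadjusted p under 0.05, 2 were lower, and 0 passed by limma adjusted over the list alone. Rplp1 and Rps16 differed by −0.27 and −0.38. Immediate early and stress genes fell as a list (39 tested, median −0.33, camera adjusted p = 0.0169, adjusted p = 0.437 with an estimated correlation), a call that ended with normexp background correction and without control array 1 or leptin array 2. The median was −0.01 with normexp background correction and −0.22 without leptin array 1. At an unadjusted p under 0.05, 5 were lower and 2 higher, and 1 fell adjusted over the list alone. This was the transcription factor Egr4, which was not well above background on either leptin array. Its bound was at least 1.58-fold lower (limma adjusted p = 0.0654), or 2.20-fold without leptin array 1 and 1.14-fold without leptin array 2. The chaperones Hspa8 and Hsp90aa1 differed by −0.15 and 0.05.

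**Figure D2:**
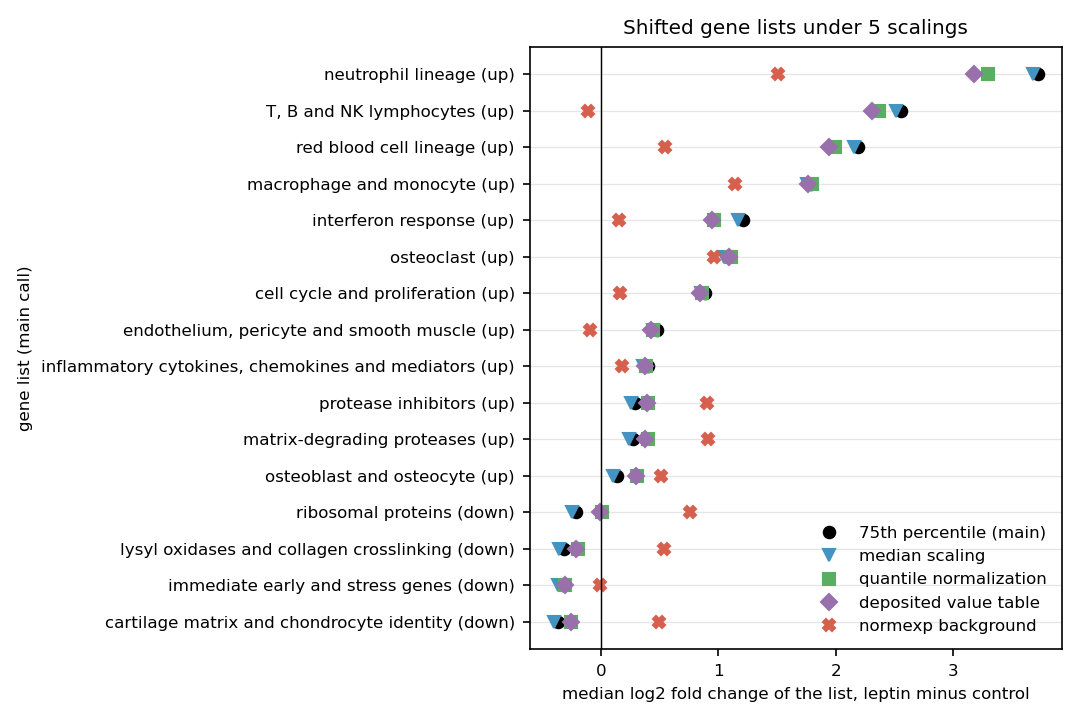
Median log2 fold change, leptin minus control (x axis), of the 16 lists that camera called, under the main 75th percentile scaling and 4 other scalings, a symbol for each. With normexp background correction the neutrophil median was 1.51, while the lymphocyte, endothelial, cartilage matrix, lysyl oxidase and ribosomal medians changed sign, and with quantile normalization the ribosomal median did.

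The other 15 lists were not called in the main test. Of these, Schwann cell genes were called downward with normexp background correction, quantile normalization and the deposited value table. Adipocyte genes were called upward with the replicate block and without control array 2 or leptin array 1, and fibroblast genes upward without control array 1 or leptin array 1. Hypertrophy genes were called downward with no filter on dim probes and without control array 1 or leptin array 1, and upward with normexp background correction. That correction also called IGF and FGF, glycolysis, oxidative phosphorylation, unfolded protein and antioxidant genes upward, while no filter on dim probes called autophagy, glycolysis, oxidative phosphorylation and unfolded protein genes downward. For leptin and JAK-STAT signalling (28 tested) the median was −0.04 (camera adjusted p = 0.703), with 1 gene higher and 2 lower at an unadjusted p under 0.05 and 0 passing by limma adjusted over the list alone. The leptin receptor, Lepr, had a log2 signal of −2.71 ± 0.17 (SD, n = 2) in controls and −1.66 ± 0.06 (SD, n = 2) with leptin, a difference of 1.05 (adjusted p = 0.0858), or of −0.26 with normexp background correction. The feedback inhibitor Socs3 differed by −0.48 (adjusted p = 0.546), or by −0.85 without leptin array 1 and −0.12 without leptin array 2, the transcription factor Stat3 by −0.19 (adjusted p = 0.735), and Bcl6 and the receptor chain Il6st by −0.20 and −0.18. Hypertrophy and mineralisation genes had a median of −0.27 (camera adjusted p = 0.145), with type X collagen, Col10a1, differing by −0.73 (adjusted p = 0.336, or by 0.24 with normexp background correction) and osteopontin, Spp1, by 0.13, or by −0.66 without control array 1 and 0.93 without control array 2. Wnt signalling had a median of −0.07 (camera adjusted p = 0.383), with 2 genes higher and 5 lower adjusted over the list alone. The Wnt inhibitor Wif1 differed by 0.12 (0.71 without control array 1 and −0.48 without control array 2) and beta-catenin, Ctnnb1, by 0.11.

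Adipocyte and lipid genes had a median of −0.04, a mean of 0.52 and an upward direction in camera (adjusted p = 0.061), with 5 higher and 1 lower adjusted over the list alone. Among them, the lipid synthesis enzymes Acly and Fasn differed by −0.17 and −0.06 and the hormone Retn by 3.31 (adjusted p = 0.0603), or by 1.45 with normexp background correction. IGF and FGF family genes had a median of −0.16, a mean of 0.13 and an upward direction in camera (adjusted p = 0.803), with 4 higher adjusted over the list alone, and Igf2 and the receptor-like Fgfrl1 differed by −0.20 and −0.19. TGF-beta and BMP signalling had a median and a mean of −0.02 and an upward direction in camera (adjusted p = 0.803), and Ccn2 and the repressor Ski differed by −0.61 and 0.14.

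Fibroblast, synovial and tendon genes had a median of 0.11 (camera adjusted p = 0.285), with 1 higher adjusted over the list alone, and Fn1, fibronectin, differed by −0.23. Skeletal muscle genes had a median of −0.15 (camera adjusted p = 0.255), with 2 lower adjusted over the list alone, and Tnni2 and Tpm2, of the thin filament, differed by −0.19 and 0.62. The muscle median was −0.01 with 3 members at their bound, 0.15 with no filter on dim probes and 0.01 with the filter on all 4 arrays. Schwann cell and nerve genes had a median of −0.13 (camera adjusted p = 0.255), and the myelin gene Pmp22 and the neuronal filament gene Prph differed by −0.52 and 0.34. Oxidative phosphorylation genes had a median of −0.02 (camera adjusted p = 0.803), with 1 lower adjusted over the list alone, and the subunits Cox6a1 and Ndufb8 differed by −0.19 and −0.07. Glycolysis and hypoxia genes had a median of −0.14 (camera adjusted p = 0.285), and the glycolytic enzyme gene Pgam1 and Higd1a differed by −0.19 and −0.14.

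Apoptosis genes had a median of 0.04 (camera adjusted p = 0.145), and the mitochondrial proteins Diablo and Cycs differed by −0.44 and 0.00. Autophagy genes had a median of −0.17 (camera adjusted p = 0.132), and Gabarap, of the autophagosome, and the mitophagy receptor Bnip3l differed by −0.17 and −0.04. Genes of the unfolded protein response had a median of −0.13 (camera adjusted p = 0.395), and the chaperone Hspa5 and the transcription factor Atf4 differed by −0.03 and −0.47. Antioxidant genes had a median of 0.04 (camera adjusted p = 0.409), and Sod3 and Gpx1, which remove superoxide and peroxides, differed by 0.11 and 0.55. The common reference genes Gapdh and Actb differed by 0.02 and 0.12, but ran from −0.09 to 0.99 and from −0.20 to 1.11 over the alternatives. Across the 128 named genes that were tested and not called, 51 changed sign with normexp background correction.

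Among single genes, 14 rose and 2 fell (limma, adjusted over the 24438 probes), and 12 of the 16 met the rule for named genes. Chi3l1, a chitinase-like glycoprotein of chondrocytes, macrophages and synovial cells (probe on chromosome 13, rn4 47146100 to 47146159), rose from a log2 signal of 2.88 ± 0.15 (SD, n = 2) to 5.29 ± 0.30 (SD, n = 2), with an adjusted p of 0.0444. Lum, a collagen-binding proteoglycan (chromosome 7, 35086409 to 35086468), rose from −0.74 ± 0.12 to 1.004 ± 0.09 (SD, n = 2, adjusted p = 0.0486). Clec10a, a lectin of macrophages and dendritic cells (chromosome 10, 57002796 to 57002855), rose 4.71-fold from −2.38 ± 0.26 to −0.15 ± 0.13 (SD, n = 2, adjusted p = 0.0444). Orm1, an acute-phase plasma protein (chromosome 5, 80326525 to 80326584), rose from −4.27 ± 0.84 to 0.47 ± 0.24 (SD, n = 2, adjusted p = 0.0444) and was well above background on 1 of the 2 control arrays, with a log2 fold change of 4.14 without control array 1 and 5.33 without control array 2, the latter against control array 1, on which it was not well above background. Pde6h, a phosphodiesterase subunit of cone photoreceptors (chromosome 4, 174014515 to 174014574), rose 5.63-fold from −3.85 ± 0.09 to −1.36 ± 0.01 (SD, n = 2, adjusted p = 0.0328). Wnt1, a secreted signalling protein (chromosome 7, 137559989 to 137560048), fell from −2.32 ± 0.05 to −5.34 ± 0.57 (SD, n = 2, adjusted p = 0.0486), at least 2.40-fold lower. This bound was 3.34-fold without leptin array 1 and 1.73-fold without leptin array 2. With normexp background correction the log2 fold changes were 3.17 for Chi3l1, 1.04 for Lum, 0.64 for Clec10a, 1.41 for Orm1, 0.11 for Pde6h and −1.21 for Wnt1.

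The other 6 genes of the rule were well above background on both leptin arrays and neither control array in the main scaling. With normexp background correction the log2 fold change of each of them was negative. Only their folds are given as bounds, and their adjusted p-values rest on the dim control signals as read. Cd2 rose at least 3.96-fold (chromosome 2, 196345785 to 196345844, adjusted p = 0.0283) and the lipoprotein receptor family gene Lrp1b at least 5.80-fold (chromosome 3, 21932971 to 21933030, adjusted p = 0.0283). Fut2, a fucosyltransferase, rose at least 2.30-fold (adjusted p = 0.0444) and Adgrb3, an adhesion receptor of the brain, at least 2.31-fold (adjusted p = 0.0444). Elavl2, a neuronal RNA-binding protein, rose at least 1.90-fold (adjusted p = 0.0347) and Adad1, a testis RNA-binding protein, at least 2.39-fold (adjusted p = 0.0328). Without leptin array 1 the bounds were 1.77-fold for Fut2 and Adgrb3, 1.59-fold for Elavl2 and 2.37-fold for Adad1. For Lrp1b and Cd2 they were 5.06-fold and 4.19-fold. Of the 12 named calls, those of Chi3l1, Clec10a, Lum, Fut2, Adgrb3 and Elavl2 ended with quantile normalization and in the deposited value table, and that of Orm1 with quantile normalization. Lum, Pde6h and Wnt1 ended with the mean of probes, and Lum with the replicate block and without leptin array 1. Only 1 of the 16 called genes had several tested probes, so for most of them the mean of probes left the values unchanged. In that setting p-values were adjusted over genes and probes without a symbol, a different set.

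**Figure D3:**
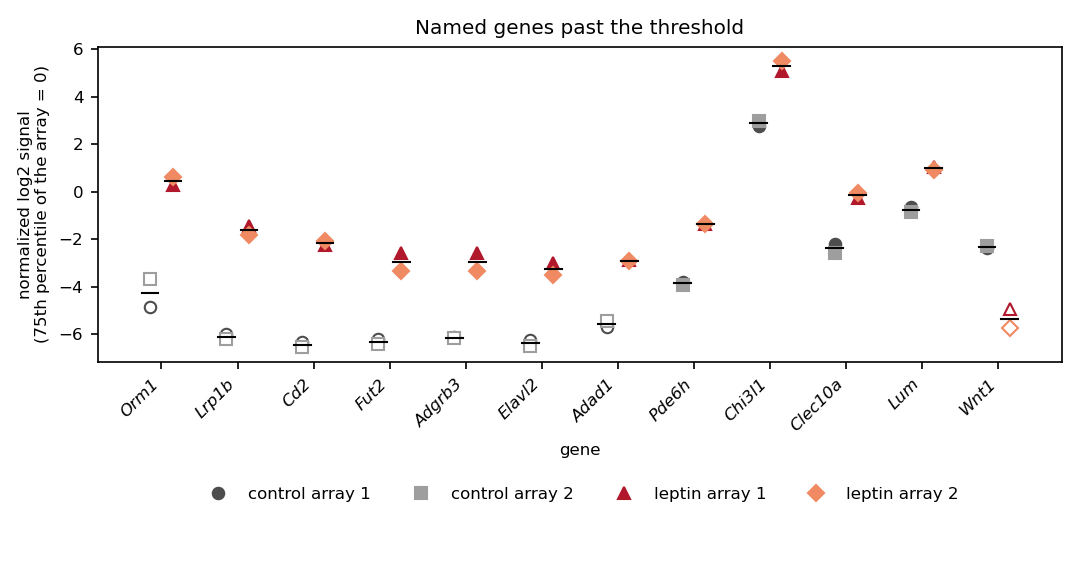
Normalized log2 signal (y axis) of the 12 named called genes on each array, with group means as black bars and open symbols where fewer than both arrays of a group were well above background. Chi3l1 had means of 2.88 in controls and 5.29 with leptin, and with normexp background correction Lrp1b, Cd2, Fut2, Adgrb3, Elavl2 and Adad1 changed direction.

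At the probe level, 66 of 24438 rose and 6 fell, and 58 of the 66 were not well above background on either control array. At an unadjusted p under 0.05 there were 3632 probes, 2072 higher and 1560 lower, where chance gives 1221.9. Quantile normalization and the deposited value table turned the balance of called probes to 13 higher and 20 lower, and 14 higher and 23 lower, and that of genes to 4 higher and 9 lower, and 5 higher and 10 lower. Without a variance model, 355 genes lay at least 2-fold higher and 56 at least 2-fold lower in every pair of arrays, which became 295 and 124 with quantile normalization, 279 and 108 in the deposited value table and 74 and 4 with normexp background correction. Both leptin arrays lay above both control arrays for 2205 genes and below for 3115, or 45.8% in group order where chance gives 33.3%, and the median log2 fold change of all genes was −0.06, against 0.05 with normexp background correction.

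By limma, 0 genes passed with normexp background correction (185 at an unadjusted p under 0.05), an eBayes variance trend (1792), a filter on all 4 arrays (1336), without control array 1 (1328) and without control array 2 (1131), while 211 passed without leptin array 1 and 556 without leptin array 2, 354 with no filter on dim probes and 66 with the replicate block. With an estimated correlation 0 of the 31 lists passed (1 at an unadjusted p under 0.05), as with fry (9, smallest adjusted p = 0.125), against 16 with the preset correlation.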

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

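The alternatives were all planned, and no test in this part was chosen only after the result was seen. The interferon, red cell, neutrophil, macrophage and osteoclast calls kept direction and threshold in all 13 alternatives other than an estimated correlation and fry, which by camera and fry gave 0 lists each (1 and 9 at an unadjusted p under 0.05) against 16. With normexp background correction limma called 0 probes (243 at an unadjusted p under 0.05), against 72, and 0 genes (185), against 16, and 78 genes lay 2-fold apart in every pair, against 411. Under it the log2 fold change turned to −0.027 for Lrp1b, −0.16 for Cd2, −0.47 for Fut2 and Adgrb3, −0.55 for Elavl2 and −0.45 for Adad1. It also turned the camera direction of 8 lists upward, autophagy short of the threshold and 7 past it, with adjusted p = 0.00555 for cartilage matrix (3.27e-06 to 0.437 over its alternatives), 0.0149 for hypertrophy (0.0108 to 0.577), 0.0157 for lysyl oxidases (0.000129 to 0.437), 0.00161 for glycolysis (0.00161 to 0.812), 1.95e-08 for oxidative phosphorylation (1.95e-08 to 0.980), 1.85e-09 for ribosomal proteins (1.61e-09 to 0.748) and 0.0128 for the unfolded protein response (0.0128 to 0.912). That of glycolysis, oxidative phosphorylation and ribosomal proteins also turned, short of the threshold, with quantile normalization (adjusted p = 0.591 for ribosomal proteins) and in the deposited value table (0.748), though in the value table the glycolysis and ribosomal medians were negative, as was the glycolysis median with quantile normalization. Called probes numbered 33 with quantile normalization and 37 in the deposited value table. No filter on dim probes gave 1402 probes, 354 genes and 1188 genes 2-fold apart, with more probes tested. The filter on all 4 arrays gave 0 probes (2682 at an unadjusted p under 0.05), 0 genes (1336) and 204 genes 2-fold apart, with 4 of the 12 called named genes tested. The variance trend gave 0 probes (3655) and 0 genes (1792), and the replicate block 183 probes and 66 genes. The numbers of the titles are not known to pair arrays, and the correlation of deviations of same-numbered arrays across probes was −0.0762. Leaving out an array gave 0 to 1130 probes, 0 to 556 genes and 673 to 1051 genes 2-fold apart in every pair, with a lone array assumed to vary like the other group. The 0 counts came without control array 1 (2851 probes and 1328 genes at an unadjusted p under 0.05) and without control array 2 (2414 and 1131), and the high counts without leptin array 1 (647 and 211) and leptin array 2 (1130 and 556). Median scaling gave 72 probes, and the gene count stayed between 12 and 17 with quantile normalization, median scaling, the deposited value table and the mean of probes, with 6 of 13, 16 of 17, 7 of 15 and 11 of 12 genes among the main 16. Signal over background limits the called genes, since 9 of the 14 higher genes were dim on both control arrays and both lower genes on both leptin arrays. The cause of these changes was not tested.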

Other observations

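The 5 tests of explanations given here were chosen only after the result was seen, and the genes named first were chosen after their values were seen. Genes of further blood cells, in no list, differed without passing the threshold (limma). The mast cell receptor chain Ms4a2 had a bound of at least 3.07-fold over control (adjusted p = 0.0898) and eosinophil peroxidase, Epx, of at least 2.18-fold (adjusted p = 0.0831). Without leptin array 1 the bounds were 1.46-fold and 1.24-fold, without leptin array 2 they were 6.46-fold and 3.85-fold, and with normexp background correction their log2 fold changes were −0.24 and −0.47. Ficolin B, Fcnb, a lectin of marrow cells, differed by 3.77 on the log2 scale (adjusted p = 0.0849) and Srgn, the proteoglycan of blood cell granules, by 4.62 (adjusted p = 0.0792). Complement C3 differed by 3.86 (adjusted p = 0.0551). In the other direction, C1qtnf3, a secreted protein of chondrocytes, differed by −1.73 (adjusted p = 0.0655) and the ribosomal protein gene Rps26 by −1.73 (adjusted p = 0.0561), or by −0.999 and −0.74 with normexp background correction. For all 7 genes the arrays of the groups did not overlap. Since they were chosen after their values were seen, this order is no evidence of a change. It held for 45.8% of all tested genes, where chance gives 33.3%.

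In the main scaling both leptin arrays lay above both control arrays for 21 of 23 neutrophil, 18 of 20 red cell and 12 of 16 lymphocyte genes. A lower share of chondrocytes that raises every other cell type alike was set against the muscle, adipocyte, Schwann cell and fibroblast lists. Their highest median was 0.112 (0.534 with normexp background correction), against 3.72 (1.51) for neutrophils. The red cell and lymphocyte medians were 0.55 and −0.11 with that correction. The comparison lists held genes bright in control cartilage, such as Fn1 (log2 signal 8.95) and Tnni2 (8.65), so they need not track other cells. The osteoclast and endothelial lists had medians of 1.08 and 0.48. The neutrophil median exceeded the highest upper quartile of the 4 comparison lists, which was 0.756, or 0.882 with normexp background correction. As far as those lists track other cells, this argues against a rise of every other cell type alike for the neutrophil list. For the red cell and lymphocyte lists the explanation stays open. A larger share of bone marrow RNA stays open. The precursor markers were picked from lists already seen to be higher, so they cannot tell it from other causes of that rise. Over the 12 tested, the lowest lineage median was 2.99, that of Klf1 among 3 red cell markers that reach down to 0.37. This median was 1.71 without leptin array 1 and 0.53 with normexp background correction. Mature blood cells alone stay open too, since the lower quartile of these markers was 3.13 but 0.46 with that correction. In addition, 6 of the 12 were well above background on both control arrays, and all 17 markers came from the fixed lists. Of the abundant genes, S100a8 differed by 4.44 (3.43 to 5.45 over the alternatives) and Hbb-b1 by 0.61 (0.21 to 1.55). A response of the joint to leptin, the injection itself and a difference in dissection also stay open, and slide and group cannot be told apart.

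Of the 66 probes called higher, 58 were not well above background on either control array. A background on the leptin slide that rises with the A content of the probe may contribute, since across 12900 probes dim on all 4 arrays the unprocessed log2 difference rose with A content in every pair of a leptin and a control array (Spearman rho 0.382 to 0.427, across probes that are not independent), against 0.0653 and −0.129 within groups. The mean A content was 39.5% in probes called higher, 20.3% in those called lower and 29.3% in all tested. In the neutrophil, red cell and lymphocyte lists it was 29.3%, 28.8% and 28.1%, close to that of all tested probes. The lymphocyte median still went from 2.55 to −0.11 with normexp background correction, so the mean A content of a list does not tell whether its rise held. A leptin response of dim genes stays open as well.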
